A study of Oryza sativa Japonica Group with 17 samples.

How the data were processed

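Roots of rice (Oryza sativa Japonica Group, cultivar Nipponbare) were profiled on the Affymetrix rice array, with 1 array for each of 17 samples. Per the labels, plants were raised in water culture to day 18 with ammonium at 1 mM as the nitrogen source. RNA was isolated with an RNeasy Plant kit and labelled with biotin through a 3' IVT Express kit, per the labels' protocols, in the same way for all 17 samples. The labels call the samples of a group biological replicates, so the p-values measure the spread between biological replicates.

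The deposited table holds 1 log2 value per probe set and sample, made by the authors with RMA (robust multi-array average), per the submitters' processing notes. The RMA software and its version are not given in the sources used here. RMA corrects background, sets the arrays of one run to a common distribution and summarises the probes of a probe set, so a level is comparable only among arrays normalized in the same run. The values fall into 2 sets. The 6 ND8037 arrays had a mean signal of 5.36 and a median of 4.70, against 5.93 and 5.39 for the other 11, and the smallest difference between quantile profiles of the sets, 0.552, exceeded the largest within a set, 0.075. The poly-A spike controls averaged 9.74 on the ND8037 arrays and 7.40 on the others, a difference of 2.33 over 24 probe sets. The hybridization spike controls averaged 10.00 and 10.04 in the ND8037 groups and 10.23 to 10.32 in the others. An offset common to all probe sets would move both kinds of control alike, so the poly-A gap has another source, which was not tested. The labels do not say that the sets were normalized apart, which is inferred here from the signal distributions. The sets also differed in the 3' minus 5' signal of actin, 4.86 on the ND8037 arrays and 2.85 on the others, a sign of RNA quality or labelling. Contrasts within a set are untouched by an offset between sets. The difference between the lines sets an effect in one set against an effect in the other. An offset cancels there, but a difference in signal scale or RNA quality need not. A comparison of NC2373 null or wild type with ND8037 null crosses them, so genotype, normalization and RNA quality or handling cannot be told apart there.

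Groups were taken from the sample titles and genotype labels. They were wild type (n = 3), gs1;2 (n = 3), NC2373 null (n = 3), NC2373 gs1;1 (n = 2), ND8037 null (n = 3) and ND8037 gs1;1 (n = 3). A null group holds plants without the insertion, segregated from a heterozygote of the same line. The comparisons, tests, gene list topics, named-gene rule and most alternatives were fixed before the data were examined. The labels list no segregated null for gs1;2, so wild type was its control. Any other difference between the gs1;2 plants and wild type thus cannot be told apart from loss of OsGS1;2.

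Of 57381 probe sets, 123 Affymetrix controls were left out and 57258 were tested, with no filter on signal. All 17 samples entered 1 fit with a mean per group in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit, eBayes), which left 11 residual degrees of freedom and took a prior of 3.83 degrees of freedom. Adjusted p-values are two-sided, Benjamini-Hochberg over all tested probe sets, and called under 0.05. Differences are log2 values with the standard error (SE) of limma. NC2373 gs1;1 holds 2 arrays and every other group 3, and their number limits the precision. The median SE was 0.0851 for the mean gs1;1 effect, 0.127 for NC2373 and 0.113 for ND8037. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

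Gene names came from the platform annotation, joined by gene identifier to a RefSeq gene table, in which all 22436 probe sets with 1 gene were found. Another 95 probe sets had several genes and were not named, and 34727 have no gene listed here. These probe sets stood for 17905 genes, of which 2457 had a name beyond a locus or clone identifier. No genome was used here, so no positions are given. The named-gene rule asked for the disrupted genes, the ammonium assimilation and transport lists, up to 4 members of each list that passed, and the 10 largest rises and 10 largest falls of each mutant. These had to be called, come from a probe set with 1 gene of described product, and show no overlap between mutant and control samples, in each line for gs1;1. A described product was read as a name other than an identifier, since the annotation used here holds no product text. Further list members are given as examples, and a gene chosen after its values were seen is marked so.

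Lists were tested with camera in limma, at a preset correlation of 0.01 and with 1 probe set per gene, the one with the highest mean signal. Adjustment was over the 23 lists with at least 5 measured genes. Membership was set from gene symbols and synonyms before any effect was tested, where the plan had named loci and product descriptions. Some genes outside the plan were added in that step, and root ferredoxin-NADP reductase was left out. The measured genes of a list are thus those with a matching name. A plastid ribosome list had no usable names and was not tested. Lists under 5 genes (nitrate uptake and reduction, amino acid transport, peroxidases, root hair) have counts only. Each camera call was repeated with a correlation estimated from the data. The fry test of limma was also run, which asks whether the genes of a list move one way and does not compare them with other genes.

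The procedure was tested on simulated data with 57258 probe sets, 100 changed by a log2 of 1 and 100 by a log2 of 2. It recovered 97.0% and 98.0% of them for the mean gs1;1 effect, with 7 unchanged probe sets called. The shares were 90.0% and 99.0% for gs1;2, with 10 unchanged probe sets among 199 calls. They were 90.0% and 97.0% for ND8037, with 16 among 203. The simulated spread was drawn independently for each probe set, so correlation between genes was not covered. Each sample correlated with the rest of its group at 0.994 to 0.997, and no samples held identical values.

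Alternatives were leaving out each array, only the groups compared, dim probe sets left out, quantile normalization of all 17 samples, centring each sample on its median, an intensity trend with robust spread, array weights, a 2-fold minimum, and other controls. Choices added after the data were seen were fits of each array set alone, gs1;2 against NC2373 null or against the mean of both controls, NC2373 gs1;1 against wild type, the ammonium assimilation list without the disrupted genes, and normalization alternatives for the lists.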

Results

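Transcript levels were measured in roots of 17 rice samples, each on its own array. Cytosolic glutamine synthetase (GS1) joins ammonium to glutamate, and rice has isoforms encoded by OsGS1;1, OsGS1;2 and OsGS1;3. NC2373 and ND8037 are insertion lines of OsGS1;1, and their homozygotes are called NC2373 gs1;1 (n = 2) and ND8037 gs1;1 (n = 3). Each was set against NC2373 null (n = 3) or ND8037 null (n = 3), plants without the insertion from the same line. The gs1;2 mutant (n = 3) is disrupted in OsGS1;2 and was set against wild type (n = 3). All grew for 18 days on 1 mM ammonium. Values are RMA signals on the log2 scale, given as mean ± SD, and differences are on the log2 scale with SE and adjusted p from limma.

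The disrupted genes were low in the samples that carry the insertions. OsGS1;1 (LOC4330649) stood at 12.12 ± 0.35 (n = 3) in NC2373 null and 8.75 ± 0.14 (n = 2) in NC2373 gs1;1, a difference of -3.37 (SE 0.236, adjusted p = 1.29e-05). In ND8037 it stood at 10.30 ± 0.42 (n = 3) in the null and 8.06 ± 0.08 (n = 3) in gs1;1, a difference of -2.24 (SE 0.211, adjusted p = 2.71e-04). The 2 lines did not differ detectably in this fall (-1.13, SE 0.317, adjusted p = 0.1415). OsGS1;2 (LOC4332108) stood at 12.44 ± 0.17 (n = 3) in wild type and 7.01 ± 0.18 (n = 3) in gs1;2, a difference of -5.43 (SE 0.141, adjusted p = 8.04e-12). Neither mutant had a called change in the other gene, with OsGS1;1 at 0.14 in gs1;2 (adjusted p = 0.7746) and OsGS1;2 at 0.11 in gs1;1 (adjusted p = 0.5723). The insertion sites are not given in the sources used here, so a signal left in a mutant does not tell whether full transcript remained.

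**Figure D1:**
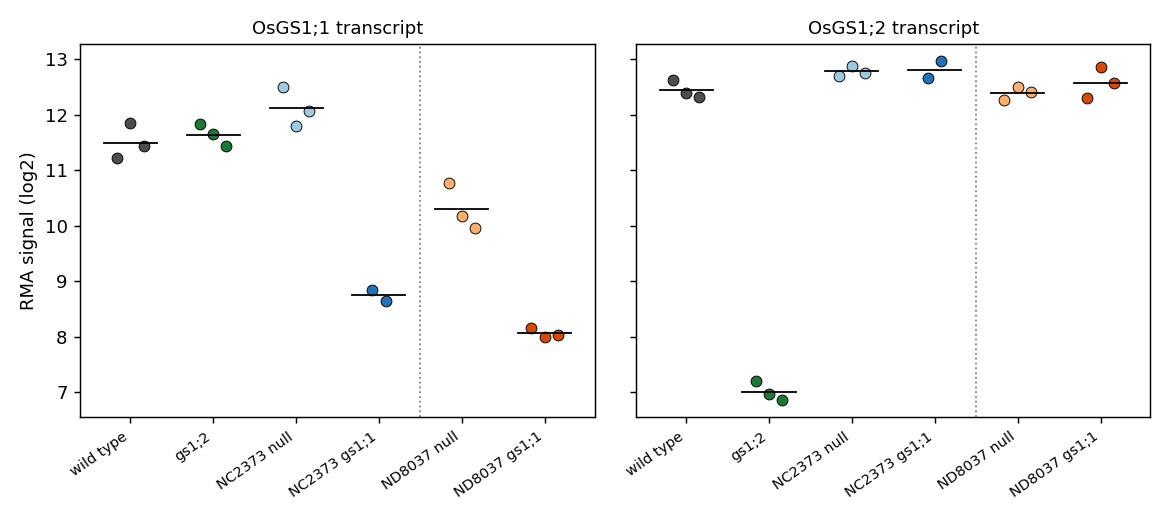
RMA signal (log2, vertical axis) of OsGS1;1 (left) and OsGS1;2 (right) in the 6 groups, with 1 point per sample and a black bar at each group mean; the dotted line parts off the ND8037 arrays, which by their values appear to have been normalized apart from the others. OsGS1;1 averaged 8.75 and 8.06 in the gs1;1 groups and 12.12 and 10.30 in their nulls, and OsGS1;2 averaged 7.01 in gs1;2 and 12.44 in wild type.

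The first comparison asked what loss of OsGS1;1 did to root transcripts, as the mean effect over both lines. Genes of the photosynthetic apparatus rose in gs1;1 roots. RCAA1, which encodes the activase of the carbon-fixing enzyme Rubisco, rose by 2.94 (SE 0.358, adjusted p = 1.71e-04), from 7.79 to 11.26 in NC2373 and from 8.11 to 10.53 in ND8037. RBCS-C, a small subunit of Rubisco, rose by 2.09 (SE 0.298, adjusted p = 4.87e-04), from 10.37 ± 0.35 (n = 3) to 12.52 ± 0.59 (n = 2) and from 9.52 ± 0.53 (n = 3) to 11.54 ± 0.98 (n = 3). LFNR1, a leaf ferredoxin-NADP reductase, rose by 2.26 (SE 0.368, adjusted p = 0.0011). Of 13 measured photosynthesis genes 9 rose, none fell and 4 were not called, with a median of 1.00 (camera adjusted p = 9.83e-07, and adjusted p = 0.55 with an estimated correlation). PSB28 of photosystem II rose by 1.72 (adjusted p = 5.65e-04). OsPSAG and RBCS-A, at 0.39 (adjusted p = 0.0920) and 0.12, were not called. Adjusted over the list alone, 12 rose. Other probe sets of RBCS-C gave 0.53, 1.75 and 0.17, and that at 0.17 was not called (adjusted p = 0.1843), while all 4 of RCAA1 lay between 2.72 and 2.94.

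Chlorophyll synthesis genes rose with them. Of 18 measured genes 13 rose and none fell, and 17 rose and 1 fell adjusted over the list alone, with a median of 0.77 (camera adjusted p = 5.85e-07, and adjusted p = 0.55 with an estimated correlation). The steps covered run from GluTR, the glutamyl-tRNA reductase that opens the pathway (0.91, adjusted p = 1.58e-04), to CAO, the oxygenase that makes chlorophyll b (0.93, adjusted p = 2.28e-04). PPOX1, a protoporphyrinogen oxidase, rose by 1.59 (adjusted p = 5.35e-04), and PORA, a light-dependent protochlorophyllide reductase, by 2.13 (SE 0.352, adjusted p = 0.0012). OsGLK1, a transcription factor known to switch on chloroplast genes, rose by 1.26.

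Of 16 measured genes of diterpenoid phytoalexins 6 rose in gs1;1 and none fell, and 9 rose adjusted over the list alone, with a median of 1.31 (camera adjusted p = 0.0012, and adjusted p = 0.55 with an estimated correlation). These defence compounds include the momilactones of rice roots. OsCPS4, which makes the momilactone precursor syn-copalyl diphosphate, rose by 2.18 (SE 0.306, adjusted p = 4.48e-04), CYP99A3 by 1.59 (adjusted p = 0.0013) and OsMAS by 1.47 (adjusted p = 0.0022). CYP701A8 rose by 2.60 (adjusted p = 0.0047), and OsKO5 of the kaurene oxidase family by 2.28 (SE 0.385, adjusted p = 0.0014). In NC2373 null OsCPS4 (6.80) lay below wild type (8.70, a difference of -1.91, adjusted p = 0.0423), with NC2373 gs1;1 at 8.77, and OsKO5 stood at 4.34, 6.31 (-1.97, adjusted p = 0.0897) and 6.78 in these groups.

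Of 22 iron acquisition genes 7 rose and 4 fell, and the list did not pass (median 0.02, mean 0.39, camera adjusted p = 0.6241). Among the rises were genes of phytosiderophores, the iron chelators that grass roots secrete. OsNAS1, a nicotianamine synthase, rose by 3.09 (SE 0.675, adjusted p = 0.0068), from 7.10 ± 1.20 (n = 3) to 10.75 ± 1.74 (n = 2) in NC2373 and from 8.28 ± 1.54 (n = 3) to 10.81 ± 0.30 (n = 3) in ND8037. OsNAS2 rose by 2.12 (SE 0.462, adjusted p = 0.0068), OsNAAT1, which acts after them, by 1.65 (adjusted p = 4.87e-04), and YSL15, the importer of the iron chelate, by 1.88 (SE 0.282, adjusted p = 6.61e-04). IRO3, a regulator of the iron response, rose by 1.32 (adjusted p = 0.0012). NC2373 null lay below wild type in OsNAAT1 (9.26 and 10.82, a difference of -1.56, adjusted p = 0.0316), with NC2373 gs1;1 at 11.12. In OsNAS1 the null and wild type stood at 7.10 and 9.74 (adjusted p = 0.2021), in OsNAS2 at 9.52 and 11.73 (adjusted p = 0.1124), with NC2373 gs1;1 at 11.98, and in YSL15 at 6.85 and 8.14 (adjusted p = 0.1254), with NC2373 gs1;1 at 9.15. Without NC2373 gs1;1 sample 117 the calls of OsNAS1 (2.47, adjusted p = 0.0512) and OsNAS2 (1.67, adjusted p = 0.0513) ended. The falls were OsYSL13 (-0.76), OsYSL14 (-0.67), YSL6 (-0.40) and OsNAS3, another nicotianamine synthase (-0.49, adjusted p = 0.0138), whose call ended without sample 117 (-0.44, adjusted p = 0.0713). Adjusted over the list alone, 8 rose and 6 fell.

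The largest named falls fell in other classes. ILL3, an IAA-amino acid hydrolase of the ILR1-like family, fell by 3.96 (SE 0.479, adjusted p = 1.63e-04), from 11.03 ± 0.24 (n = 3) to 6.31 ± 1.32 (n = 2) and from 10.16 ± 0.57 (n = 3) to 6.96 ± 1.20 (n = 3). OsICL, the isocitrate lyase of the glyoxylate cycle, fell by 3.78 (SE 0.347, adjusted p = 3.17e-05), from 8.46 to 4.51 and from 8.60 to 4.99. OsGLU6 changed by -3.50 (SE 0.413), the actin-depolymerizing factors OsADF9 and OsADF6 by -2.41 (SE 0.230) and -1.42 (SE 0.218), the peroxiredoxin R1C-Prx by -2.13 (SE 0.287), ML by -1.53 (SE 0.240) and the beta-glucosidase BGLU12 by -1.44 (SE 0.166), with adjusted p between 3.96e-05 and 8.78e-04. NC2373 null lay above wild type in OsADF9 (6.09 and 3.94, a difference of 2.15, adjusted p = 0.0061) and OsADF6 (6.09 and 4.69, 1.41, adjusted p = 0.0343), with NC2373 gs1;1 at 2.92 and 4.33, and also in BGLU12 (1.03, adjusted p = 0.0424). A gene named peroxidase (LOC4344277) changed by -1.45 (SE 0.429, adjusted p = 0.0359), a call lost without NC2373 gs1;1 sample 117 (adjusted p = 0.1005), and also without any one of the other arrays but NC2373 null sample 154, ND8037 gs1;1 sample 123 and ND8037 null sample 158 (adjusted p from 0.0583 to 0.0931). Among the largest rises were also the beta-glucosidase BGLU5 at 2.23 (SE 0.253, adjusted p = 1.18e-04) and PDX12 at 2.22 (SE 0.177, adjusted p = 9.39e-06), in which NC2373 null lay above wild type by 1.09 (adjusted p = 0.0444).

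Ammonium assimilation and uptake moved in both directions. Of 9 measured assimilation genes 2 rose and 2 fell, counts that were the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.6993). Plastid OsGS2 rose by 1.27 (adjusted p = 7.93e-04) and GLT2, a glutamate synthase, by 0.67 (adjusted p = 0.0476), which was not called without NC2373 gs1;1 sample 118 (0.35, adjusted p = 0.2854) or any one other array but sample 117 (adjusted p from 0.0630 to 0.0893). The falls were OsGS1;1 and OsGDH1, a glutamate dehydrogenase, at -0.44 (adjusted p = 0.0050). OsGS1;3 stood at -0.08 (adjusted p = 0.7171). Of 8 ammonium transporters 2 rose and 1 fell, again the same adjusted over the list alone (camera adjusted p = 0.5769). AMT2-1 rose by 0.81 (adjusted p = 0.0086), AMT2-3 by 0.48 (adjusted p = 0.0478), and AMT3-2 changed by -0.59 (adjusted p = 0.0012). AMT2-3 was not called without NC2373 gs1;1 sample 117 (0.35, adjusted p = 0.2235) or any one other array but NC2373 gs1;1 sample 118, ND8037 gs1;1 sample 125 and ND8037 null sample 158 (adjusted p from 0.0510 to 0.1144). The nitrate reductase gene NIA1 rose by 0.87 (adjusted p = 0.0130), with another probe set at -0.03 that was not called, and OsNAR2.2, a partner of nitrate transporters, changed by -0.65 (adjusted p = 0.0036).

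In the cytosolic ribosome list 11 of 24 rose and none fell, with 19 higher adjusted over the list alone (median 0.27, camera adjusted p = 1.15e-06, and adjusted p = 0.55 with an estimated correlation). The lines differed in this list (camera adjusted p = 4.78e-08, and adjusted p = 0.7835 with an estimated correlation), with a median of -0.0043 and 1 of 24 higher in NC2373 and a median of 0.53 and 19 of 24 higher in ND8037, where the 3' minus 5' signal of GAPDH also differed by -0.22 (SD 0.08) between gs1;1 and its null. RPL27 rose by 0.84 (adjusted p = 0.0051), RPL9 by 0.38 (adjusted p = 0.0096) and 60SP0 by 0.37 (adjusted p = 0.0162). In the DNA replication and cell cycle list 8 of 29 rose and 1 fell, the same adjusted over the list alone (median 0.21, camera adjusted p = 0.0201, and adjusted p = 0.7055 with an estimated correlation). The histone gene H2B.5 rose by 0.44, OsMCM3 of the replication helicase by 0.47 and CYCB2-2, a mitotic cyclin, by 0.50, while CYCD2-2 changed by -0.34. The median of this list was -0.0035 in NC2373 and 0.45 in ND8037, a difference between lines that passed as well (adjusted p = 0.0031, and adjusted p = 0.7835 with an estimated correlation). In both lists the lines also differ in array set, so line and array set cannot be told apart.

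The remaining lists did not pass in gs1;1. In the cytokinin list 8 of 26 rose and 3 fell, and 11 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.1164), with the cytokinin-degrading OsCKX4 at 1.52, the response regulator OsRR4 at 1.03 and OsCKX3 at -0.82. In sucrose breakdown and glycolysis 1 of 31 rose and 5 fell, or 1 and 6 adjusted over the list alone (adjusted p = 0.5724), among them the invertase OsCIN2 at -1.40 and the hexokinase HXK6 at -0.93. In starch metabolism 3 of 15 rose by both adjustments (adjusted p = 0.2814), led by AGPS2, a subunit of ADP-glucose pyrophosphorylase, at 1.14. Of 9 shikimate genes 5 rose and 2 fell by both adjustments (adjusted p = 0.3477), with the anthranilate synthases OASB1 at 0.73 and OASA1 at -0.53. Of 25 phenylpropanoid and lignin genes 3 rose and 2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.3737), the laccases LAC10 at 1.18 and LAC7 at -0.73 among them. Heat shock genes moved both ways, 6 of 50 up and 5 down, or 10 and 7 adjusted over the list alone (adjusted p = 0.7043).

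Smaller counts came from the other lists. Carbon skeleton genes had 1 rise and 2 falls among 15, the same adjusted over the list alone (adjusted p = 0.1164), phosphate starvation genes 2 and 1 among 16, or 2 and 2 (adjusted p = 0.5724), and pathogenesis-related genes 1 and 0 among 11, or 1 and 2 (adjusted p = 0.9054). Among 22 casparian strip genes 1 rose and 4 fell, or 2 and 7 adjusted over the list alone (adjusted p = 0.5724). Of 7 secondary wall genes 2 fell, or 1 rose and 4 fell adjusted over the list alone (adjusted p = 0.3012), with BC1 at -1.02 and CESA7 at -0.46. Cell wall loosening genes had 2 falls among 30, or 1 adjusted over the list alone (adjusted p = 0.4406), glutathione S-transferases 1 among 6, or 2 (adjusted p = 0.2814), and seed storage genes 1 among 8, or 2 (adjusted p = 0.5724). The low oxygen list had no call in limma, by either adjustment, with 1 of 7 genes higher and 2 lower at an unadjusted p under 0.05 (adjusted p = 0.5724). Of lists too short to test, peroxidases had 1 fall among 3, root hair genes had no call and no unadjusted p under 0.05 among 3, and of 2 amino acid transporters PROT1 changed by -0.23 (adjusted p = 0.0355).

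In all, limma called 7991 of 57258 probe sets in gs1;1, 3933 higher and 4058 lower, of which 860 differed by at least 2-fold. Mutant and null samples did not overlap in either line for 2454 higher probe sets (4.29%) and 3052 lower ones (5.33%), where chance gives 0.50% each. Without NC2373 gs1;1 sample 117 the count of calls was 5260, a fall of over 1.5 times.

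**Figure D2:**
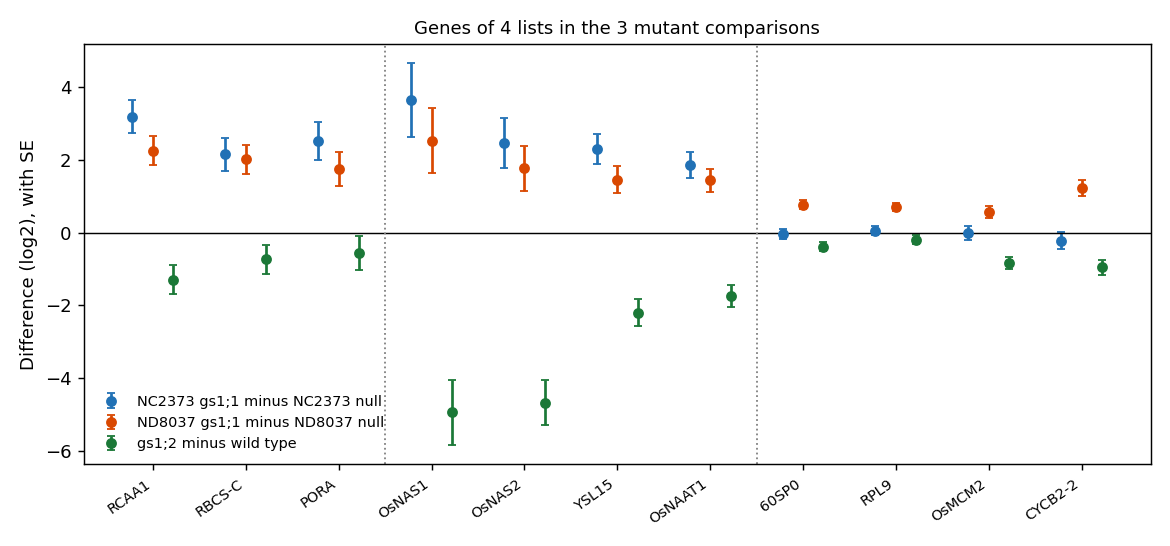
Difference (log2, vertical axis) of genes from 4 lists in NC2373 gs1;1 minus its null (blue), ND8037 gs1;1 minus its null (orange) and gs1;2 minus wild type (green), as points with SE bars. OsNAS1 lay at 3.65 and 2.53 in the gs1;1 lines and -4.94 in gs1;2, and 60SP0 at -0.03, 0.77 and -0.38.

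Taken alone, NC2373 asked whether the gs1;1 effect held in that line. RCAA1 rose from 7.79 to 11.26 in it, and the photosynthesis list had a median of 1.28, with 8 of 13 genes higher and 11 adjusted over the list alone (camera adjusted p = 3.08e-07, and adjusted p = 0.5602 with an estimated correlation). Chlorophyll synthesis had 11 of 18 higher, and 15 higher and 1 lower adjusted over the list alone (median 0.69, camera adjusted p = 3.08e-07, and adjusted p = 0.5602 with an estimated correlation). Cytokinin genes passed here, with 7 of 26 higher and 1 lower, 9 and 2 adjusted over the list alone (median 0.19, camera adjusted p = 0.0031, and adjusted p = 0.5602 with an estimated correlation). OsCKX4 rose by 2.57 (adjusted p = 0.0032), LOGL6, a cytokinin-activating enzyme, by 1.33 (adjusted p = 0.0023), and OsCKX3 changed by -0.93. Phytoalexin genes had 1 of 16 higher and 6 adjusted over the list alone (median 1.24, camera adjusted p = 0.0020, and adjusted p = 0.7638 with an estimated correlation). In the carbon skeleton list PDHE1-A (LOC4340640) rose by 0.77 and 3 succinate dehydrogenase genes fell, among them SDH5 (-0.47) and SDH7 (-0.44), or 1 and 7 adjusted over the list alone (median -0.28, camera adjusted p = 0.0148). Cell wall loosening had 3 of 30 lower, the expansins OsEXPB18 (-2.44) and EXPA16 (-0.71) and XTH8 (-0.41), with camera adjusted p = 0.0499, and 0.0665 after quantile normalization. Both lists had adjusted p = 0.7638 with an estimated correlation. Limma called 4382 probe sets (2330 higher, 2052 lower), and the count fell to 1525 without sample 117, 1594 without sample 118, 2067 without null sample 152 and 2189 with only the compared groups in the fit. Without sample 117 the calls of RBCS-C (1.74, adjusted p = 0.1104), LFNR1 (2.32, adjusted p = 0.0961), PORA (2.10, adjusted p = 0.1072), PSB28 (1.64, adjusted p = 0.0727) and PPOX1 (1.27, adjusted p = 0.1350) ended in this line, while RCAA1 stayed called without any single array. Without sample 117 or 118 the calls of OsEXPB18 (adjusted p = 0.0737 and 0.0738), EXPA16 (0.1008 and 0.0713), XTH8 (0.2007 and 0.0622), PDHE1-A (0.0694 and 0.1690), SDH5 (0.1673 and 0.1592) and SDH7 (0.1399 and 0.2442) ended. Null sample 152 also decided XTH8 (0.0876), PDHE1-A (0.0862), SDH5 (0.1376) and SDH7 (0.1781), sample 153 SDH5 (0.0628) and SDH7 (0.0747), and sample 154 XTH8 (0.0525) and SDH5 (0.0530).

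Taken alone, ND8037 passed the ribosome and cell cycle lists. Of 24 cytosolic ribosome genes 19 rose and none fell, and 23 rose adjusted over the list alone (median 0.53, camera adjusted p = 5.22e-12, and adjusted p = 0.7408 with an estimated correlation). The ribosomal gene 60SP0 rose by 0.77 (adjusted p = 0.0036), from 10.30 ± 0.11 (n = 3) to 11.07 ± 0.17 (n = 3), RPL9 by 0.70 (adjusted p = 0.0040), RPL5 by 0.78 (adjusted p = 0.0055) and RPS26 by 0.74 (adjusted p = 0.0056). Of 29 DNA replication and cell cycle genes 10 rose, and 16 rose and 2 fell adjusted over the list alone (median 0.45, camera adjusted p = 8.35e-05, and adjusted p = 0.7408 with an estimated correlation). H2B.11 rose by 0.62 (adjusted p = 0.0024), CYCB2-2 by 1.23 (adjusted p = 0.0046) and OsMCM3 by 0.89 (adjusted p = 0.0128). The 3' minus 5' signal of GAPDH, a sign of RNA integrity, differed by -0.22 between ND8037 gs1;1 and its null, against a spread of 0.08 (SD, n = 3; exact two-sided permutation p = 0.10, the smallest these samples can give), and that of actin differed by 0.03 (SD 0.12). Chlorophyll synthesis had 5 of 18 higher and 11 adjusted over the list alone (median 0.58, camera adjusted p = 4.88e-04, and adjusted p = 0.7408 with an estimated correlation). Photosynthesis had 4 of 13 higher and 8 adjusted over the list alone (median 0.80, camera adjusted p = 8.19e-04, and adjusted p = 0.7408 with an estimated correlation). Phytoalexins had 4 of 16 higher and 5 adjusted over the list alone (median 1.15, camera adjusted p = 0.0307, and adjusted p = 0.7924 with an estimated correlation). Without gs1;1 sample 123 the calls of LFNR1 (1.36, adjusted p = 0.1227), PORA (1.29, adjusted p = 0.1439) and PSB28 (0.89, adjusted p = 0.0673) ended in this line. LFNR1 was also lost without null sample 156, 157 or 158, and PSB28 without 156 or 157. PORA was lost as well without gs1;1 sample 124 or null sample 156 or 158. CYP701A8 was lost without gs1;1 sample 124 or 125 or null sample 156 or 157. OsNAS1 at 2.53 (adjusted p = 0.0934) and OsNAS2 at 1.77 (adjusted p = 0.0863) did not pass in this line alone. Limma called 5200 probe sets (2520 higher, 2680 lower), and 2075 without gs1;1 sample 123, 3213 without gs1;1 sample 125, 2449 without null sample 157, 2782 without null sample 158 and 3213 with only the compared groups in the fit.

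Whether the lines differed in their gs1;1 effect was tested directly, as the NC2373 effect minus the ND8037 effect. Each line lies in its own array set, and the sets differ in signal distribution and in the 3' minus 5' signal of actin. A common offset cancels in this test, but other differences between the sets cannot be told apart from line. Ribosome genes had the smallest p of the lists, with a median of -0.51 (camera adjusted p = 4.78e-08), from medians of -0.0043 in NC2373 and 0.53 in ND8037. DNA replication and cell cycle differed by a median of -0.40 (adjusted p = 0.0031), cell wall loosening by -0.49 (adjusted p = 0.0123), carbon skeletons by -0.20 (adjusted p = 0.0369) and cytokinin by 0.24 (adjusted p = 0.0043). All 5 calls had adjusted p = 0.7835 with an estimated correlation. Limma called 0 members of these lists over all probe sets, though at an unadjusted p under 0.05 it had 19 ribosome, 15 cell cycle, 8 cell wall and 3 carbon skeleton genes lower and 7 cytokinin genes higher. Adjusted over the list alone, 19 ribosome genes, 12 cell cycle genes and 5 cell wall genes were lower, 2 cytokinin genes were higher and 0 carbon skeleton genes were called. The photosynthesis list differed by 0.55 (adjusted p = 0.0610), and passed after quantile normalization (0.0445) and after centring (0.0491). Limma called 5 probe sets over all, against 9136 at an unadjusted p under 0.05, and 102 with only the compared groups in the fit. The 5 are named here after their values were seen. LOC4327573 differed by 1.91 (SE 0.262, adjusted p = 0.0409), with 2.22 in NC2373 and 0.32 in ND8037, and the calmodulin gene OsCAM-2 by -1.55 (SE 0.205, adjusted p = 0.0409), with -0.94 and 0.61. The other 3 have no gene listed here and differed by 1.67 (SE 0.179, adjusted p = 0.0080), 0.78 (adjusted p = 0.0409) and -1.94 (adjusted p = 0.0491). The count rose to 22 without ND8037 gs1;1 sample 123 and fell to 1 without any one of ND8037 gs1;1 samples 124 and 125, ND8037 null samples 157 and 158, or NC2373 null sample 153. It was 2 without NC2373 null sample 154 or ND8037 null sample 156, and 3 without NC2373 null sample 152 or NC2373 gs1;1 sample 118.

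Of probe sets called in each line, 636 were higher in both, where independent lists would share 102.5, and 567 were lower in both (96.0 if independent). Only 1 was higher in NC2373 and lower in ND8037 (109.1 if independent) and 7 the reverse (90.3). Across probe sets, which are not independent replicates, the effects of the lines correlated with Pearson's r of 0.446 and Spearman's rho of 0.248. The lines share no control samples.

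The next comparison asked what loss of OsGS1;2 did to root transcripts, against wild type. Wild type is not a segregated null, so a background difference between the gs1;2 plants and wild type cannot be told apart from that loss. The largest named falls besides OsGS1;2 were those of the nicotianamine synthases OsNAS1 and OsNAS2. OsNAS1 fell by 4.94 (SE 0.900, adjusted p = 0.0080), from 9.74 ± 0.45 (n = 3) to 4.80 ± 1.83 (n = 3), and OsNAS2 fell by 4.68 (SE 0.616, adjusted p = 9.41e-04), from 11.73 ± 0.27 (n = 3) to 7.05 ± 1.11 (n = 3). YSL15 fell by 2.20 (SE 0.376, adjusted p = 0.0054) and OsNAAT1 by 1.74 (adjusted p = 0.0076), from 10.82 ± 0.27 (n = 3) to 9.08 ± 0.58 (n = 3). OsIRT1, a transporter of ferrous iron, rose instead by 1.27 (SE 0.224, adjusted p = 0.0065). In the iron list 1 of 22 rose and 5 fell, or 2 and 7 adjusted over the list alone. The list did not pass, and its parts differ in sign, with a median of 0.04, a mean of -0.57 and a camera test that leaned up (adjusted p = 0.9928). Against NC2373 null, a control added after the data were seen, OsNAS2 stood at -2.47 (adjusted p = 0.0206), and OsNAS1 at -2.30 (adjusted p = 0.1204), YSL15 at -0.91 (adjusted p = 0.1423) and OsNAAT1 at -0.18 (adjusted p = 0.7743) were not called.

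The other 6 of the largest named falls, which belong to no list fixed beforehand, were single genes. The jasmonate repressors OsJAZ13 and OsJAZ3 fell by 3.42 (SE 0.543, adjusted p = 0.0034) and 3.33 (SE 0.560, adjusted p = 0.0048). DREB1G and CBF3, transcription factors of the cold-responsive DREB1 family, fell by 3.34 (SE 0.661, adjusted p = 0.0121) and 2.36 (SE 0.486, adjusted p = 0.0150), OsTPP1, a trehalose-6-phosphate phosphatase, by 2.35 (SE 0.383, adjusted p = 0.0040) and BHLH148 by 2.19 (SE 0.426, adjusted p = 0.0111). Against NC2373 null, OsTPP1 was called lower (-1.30, adjusted p = 0.0434) and the other 5 were not, with adjusted p from 0.1169 for DREB1G to 0.7064 for CBF3 (-0.36). Without gs1;2 sample 356 the calls of DREB1G (-3.25, adjusted p = 0.0643), CBF3 (-2.40, adjusted p = 0.0643) and BHLH148 (-2.20, adjusted p = 0.0529) ended. CBF3 was also lost without wild type samples 627 (adjusted p = 0.0625) and 628 (adjusted p = 0.0582), and BHLH148 without wild type sample 628 (adjusted p = 0.0518). With only the compared groups in the fit, OsJAZ3 (adjusted p = 0.0596) and BHLH148 (adjusted p = 0.0909) were not called.

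The largest named rise was that of OsHAK17, a potassium transporter gene. It rose by 3.22 (SE 0.512, adjusted p = 0.0034), from 5.87 ± 0.62 (n = 3) to 9.09 ± 0.34 (n = 3), and OsHAK5, of the same family, by 1.58 (SE 0.341, adjusted p = 0.0192). The defence regulator OsWRKY62 rose by 2.20 (SE 0.355, adjusted p = 0.0037), the laccase LAC24 by 2.13 (SE 0.209, adjusted p = 6.57e-05), from 9.33 to 11.46, and the RNA helicase RH2 by 1.95 (SE 0.314, adjusted p = 0.0037). BGLU22, a beta-glucosidase, rose by 1.45 (SE 0.219, adjusted p = 0.0026), the sucrose transporter OsSUT1 by 1.34 (SE 0.237, adjusted p = 0.0065) and the amino acid transporter BAT1 by 1.33 (SE 0.279, adjusted p = 0.0170). Against NC2373 null, with the same gs1;2 arrays, 8 of the 10 named rises were called higher, and OsSUT1 (0.52, adjusted p = 0.1840) and BAT1 (0.82, adjusted p = 0.0735) were not. OsHAK5 and BAT1 were lost without gs1;2 sample 356 (adjusted p = 0.1040 and 0.0895), gs1;2 sample 355 (0.0653 and 0.0538) or wild type sample 627 (0.0572 and 0.0701), and BAT1 also without wild type sample 628 (0.0814). With only the compared groups in the fit, OsHAK5 (adjusted p = 0.1157), OsSUT1 (0.0811) and BAT1 (0.1016) were not called.

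In the DNA replication and cell cycle list 8 of 29 genes fell in gs1;2 and none rose, with 15 lower adjusted over the list alone (median -0.38, camera adjusted p = 0.0041, and adjusted p = 0.6375 with an estimated correlation). The replication helicase genes OsMCM7, OsMCM4 and OsMCM2 changed by -0.98 (adjusted p = 0.0055), -0.94 (adjusted p = 0.0112) and -0.84 (adjusted p = 0.0122), and CYCB2-2 by -0.95 (adjusted p = 0.0216). Without gs1;2 sample 356, wild type sample 627 or wild type sample 628 the calls of OsMCM2 (adjusted p = 0.0730, 0.0524 and 0.0549) and CYCB2-2 (0.1102, 0.0566 and 0.0985) ended, the latter also without gs1;2 sample 355 (0.0580), and OsMCM7 (0.0559) and OsMCM4 (0.1028) were lost with only the compared groups in the fit. In the heat shock list 5 of 50 genes rose, none fell and 45 were not called, with 8 higher and 5 lower adjusted over the list alone (median 0.09, camera adjusted p = 0.0041, and adjusted p = 0.4092 with an estimated correlation). HSP18.6, a small heat shock protein, rose by 2.01 (SE 0.133, adjusted p = 8.40e-07), from 5.10 ± 0.09 (n = 3) to 7.11 ± 0.26 (n = 3), HSP17.9A by 0.72 and HSP24.1 by 0.60. HSP17.9A was not called without any one of the compared arrays but gs1;2 sample 354 (adjusted p from 0.0506 to 0.1108). Of 24 ribosome genes RPS10-1 fell (-0.53, adjusted p = 0.0435, lost without any one of the 6 arrays, at 0.0523 to 0.1755), and 4 fell adjusted over the list alone (median -0.21, camera adjusted p = 0.0162, and adjusted p = 0.6375 with an estimated correlation). Carbon skeleton genes had a median of -0.20 (camera adjusted p = 0.0176, and adjusted p = 0.6375 with an estimated correlation). Limma called 0 of the 15, by either adjustment, and 6 lay lower at an unadjusted p under 0.05. Of 22 casparian strip genes 2 rose and 1 fell, or 5 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.0176, and adjusted p = 0.4092 with an estimated correlation), with OsCASPL1U2 at 0.93, which was not called without gs1;2 sample 356 (adjusted p = 0.0598). Phytoalexins passed with a median of 0.24 (camera adjusted p = 0.0485, and adjusted p = 0.6375 with an estimated correlation), though limma called 0 of 16 by either adjustment, with 1 at an unadjusted p under 0.05, and the list did not pass after quantile normalization (0.1365). Against NC2373 null the DNA replication and cell cycle list (median -0.13, camera adjusted p = 0.0515, 1 gene higher and 14 lower), heat shock (median 0.05, adjusted p = 0.0594, 4 higher and 4 lower), carbon skeletons (median -0.18, adjusted p = 0.0594) and casparian strip (median 0.13, adjusted p = 0.0782) did not pass. Ribosome genes (median -0.29, adjusted p = 0.0044, and adjusted p = 0.6397 with an estimated correlation) and phytoalexins (median 0.91, adjusted p = 0.0062, and adjusted p = 0.5590 with an estimated correlation) did.

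The ammonium assimilation list holds the disrupted gene. Of its 9 genes 2 were lower in gs1;2 and 3 adjusted over the list alone (median -0.31, camera adjusted p = 0.0183, and adjusted p = 0.4092 with an estimated correlation). With OsGS1;1 and OsGS1;2 left out, a choice made after the data were seen, the 7 other genes did not pass (median -0.31, camera adjusted p = 0.1727). Besides OsGS1;2 the called fall was OsGDH1 at -0.52 (adjusted p = 0.0273), which was lost without wild type sample 629 (-0.37, adjusted p = 0.0691), gs1;2 sample 355 (adjusted p = 0.0828) or gs1;2 sample 356 (adjusted p = 0.1330). Against NC2373 null the list passed with the disrupted gene (median -0.46, camera adjusted p = 0.0070, and adjusted p = 0.5106 with an estimated correlation) and the 7 other genes did not (median -0.43, adjusted p = 0.1317). Of 8 ammonium transporters AMT2-3 fell (-0.89, adjusted p = 0.0252, lost without any one of the compared arrays but wild type sample 629, at 0.0616 to 0.1038), and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.2980). OsNAR2.2 rose by 0.69 (adjusted p = 0.0342).

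Photosynthesis and chlorophyll genes, which rose in gs1;1, gave no called list in gs1;2. The photosynthesis list had a median of -0.30 with 0 of 13 genes called in limma by either adjustment and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.4516). RCAA1 is the exception, since the list test used another of its probe sets. The one given above for its rise of 2.94 in gs1;1 was called lower in gs1;2 (-1.84, adjusted p = 0.0435). Chlorophyll synthesis had a median of -0.30 with 0 of 18 called, 1 higher and 3 lower adjusted over the list alone and 1 higher and 4 lower at an unadjusted p under 0.05 (adjusted p = 0.1727). In phosphate starvation 2 of 16 rose by both adjustments (adjusted p = 0.1727), the transporter PHT1-2 at 1.05 (adjusted p = 0.0033) and OsSPX2 at 0.91. In sucrose breakdown and glycolysis 3 of 31 fell, or 3 rose and 6 fell adjusted over the list alone (adjusted p = 0.1727), with OsCIN2 at -1.89 (adjusted p = 0.0063) and the sucrose synthase OsSUS1 at -0.75. The chitinases Cht3 (0.72) and Cht10 (-0.97) were the calls among 11 pathogenesis-related genes (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.2169). LAC24 and OsCAD8A (-0.65) were those among 25 phenylpropanoid genes, by both adjustments (adjusted p = 0.3662). Shikimate genes had 1 fall among 9, or 3 adjusted over the list alone (adjusted p = 0.1727), cell wall loosening 1 among 30, or 4 (adjusted p = 0.1727), and cytokinin 1 among 26, or 2 rises and 2 falls (adjusted p = 0.6526). The cytokinin list had a median of -0.12 and a camera test that leaned up. Starch (0.6109), glutathione S-transferase (0.4640), low oxygen (0.9928), secondary wall (0.9024) and seed storage (0.5650) lists, with camera adjusted p in parentheses, had no call in limma by either adjustment, and 1, 0, 0, 1 and 2 genes at an unadjusted p under 0.05. Of lists too short to test, peroxidases and root hair genes had no call and 1 fall each adjusted over the list alone (1 each at an unadjusted p under 0.05), and 2 amino acid transporters both rose adjusted over the list alone.

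Limma called 2310 probe sets in gs1;2, 954 higher and 1356 lower, of which 570 differed by at least 2-fold. The share that was higher, 41.3%, was 50.6% after quantile normalization and 34.9% after centring. Samples did not overlap for 7578 higher probe sets (13.23%) and 6716 lower ones (11.73%), where chance gives 5.00% each. The count was 555 without gs1;2 sample 356, 1024 without gs1;2 sample 355, 878 without wild type sample 628 and 1137 without wild type sample 627, and it was 615 with only the compared groups in the fit and 1360 with one array set alone. Against NC2373 null 5849 were called, and 889 of the 2310 calls ended.

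Whether loss of OsGS1;1 and of OsGS1;2 differed was tested as the difference of their effects, each against its own control. On the gs1;2 side, background and loss of OsGS1;2 cannot be told apart, as its control was not a segregated null. Named genes called in opposite directions were sought with 1 probe set per gene, the one with the highest mean signal. This left out a probe set of RCAA1 called higher in gs1;1 (2.94) and lower in gs1;2 (-1.84). Its effects differed by 4.78 (SE 0.596, adjusted p = 3.81e-04). Among the genes sought so, the largest differences were in 4 genes of the iron acquisition list. That list did not pass, with 7 of 22 genes higher in gs1;1 and 5 lower, or 7 and 7 adjusted over the list alone (median -0.09, mean 0.96, camera adjusted p = 0.9265). OsNAS1 differed by 8.02 (SE 1.12, adjusted p = 8.05e-04), OsNAS2 by 6.79 (SE 0.77, adjusted p = 1.76e-04), YSL15 by 4.08 (SE 0.47, adjusted p = 1.98e-04) and OsNAAT1 by 3.39 (SE 0.39, adjusted p = 2.10e-04), each higher in gs1;1 and lower in gs1;2. The opposite calls depend on the control. Against NC2373 null, gs1;2 was called lower in OsNAS2 (-2.47, adjusted p = 0.0206). It was not in OsNAS1 (-2.30, adjusted p = 0.1204), YSL15 (-0.91, adjusted p = 0.1423) or OsNAAT1 (-0.18, adjusted p = 0.7743). The rise of OsNAS2 in NC2373 also depends on the control, with gs1;1 at 11.98, its null at 9.52 and wild type at 11.73. LAC24 differed by -2.75 (SE 0.26, adjusted p = 5.02e-05) and OsSUT1 by -2.10 (SE 0.30, adjusted p = 8.53e-04), each lower in gs1;1 and higher in gs1;2. With NC2373 null as the control of gs1;2, LAC24 was called higher (1.79, adjusted p = 2.61e-04) and OsSUT1 was not (0.52, adjusted p = 0.1840). The gs1;1 falls of LAC24 and OsSUT1 were called in ND8037 (adjusted p = 0.0168 and 0.0492). In NC2373 neither was (-0.35, adjusted p = 0.4547, and -0.71, adjusted p = 0.1267). With that choice of probe set, 44 named genes were called in opposite directions with a called difference. Among them were OsCKX5 (0.81 and -0.79), the aquaporin OsPIP1;3 (0.69 and -0.76), AMT2-3, OsNAR2.2, OsPCNA and CYCB2-2. The calls of AMT2-3 in both mutants and of CYCB2-2 in gs1;2 were lost without any one of several arrays, as given above.

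Gene lists separated the mutants as well. Photosynthesis differed by a median of 1.56, with 8 of 13 genes higher in gs1;1 and 10 adjusted over the list alone (camera adjusted p = 9.72e-05), and ribosome genes by 0.50, with 13 of 24 and 18 (adjusted p = 2.78e-06). Both had adjusted p = 0.4209 with an estimated correlation. Chlorophyll synthesis differed by 0.87, with 9 of 18 and 14 adjusted over the list alone (adjusted p = 1.05e-05), and DNA replication and cell cycle by 0.47, with 12 of 29, or 18 higher and 1 lower adjusted over the list alone (adjusted p = 7.59e-05). These had adjusted p = 0.3954 with an estimated correlation. On the gs1;1 side the ribosome and cell cycle lists rose in ND8037 (medians 0.53 and 0.45) and not in NC2373 (-0.0043 and -0.0035). Between the ND8037 groups the 3' minus 5' signal of GAPDH also differed, by -0.22 (SD 0.08). Heat shock and casparian strip, which leaned down at adjusted p = 0.0509 each, passed after centring (0.0448 each). Limma called 5581 probe sets, 3181 higher and 2400 lower, or 2773 and 2769 after quantile normalization and 3505 and 2026 after centring. Without gs1;2 sample 356 it called 3151. Of the probe sets called for each mutant, 255 were higher in gs1;1 and lower in gs1;2 (93.1 if independent), 149 the reverse (67.6), 144 higher in both (65.5) and 88 lower in both (96.1). The effects correlated across probe sets with r of -0.0917 and rho of -0.0628, and share no controls.

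As background to the lines, NC2373 null was set against wild type. Photosynthesis genes were higher in the null, 3 of 13 and 9 adjusted over the list alone (median 1.04, camera adjusted p = 3.56e-06, and adjusted p = 0.6686 with an estimated correlation), with RBCS-C at 1.93 (adjusted p = 0.0340) and OsPSAG at 0.95 (adjusted p = 0.0316). Chlorophyll synthesis had 2 of 18 higher and 6 adjusted over the list alone (median 0.27, adjusted p = 1.11e-04, and adjusted p = 0.6686 with an estimated correlation), with CAO at 1.08 (adjusted p = 0.0068). The secondary wall cellulose synthases CESA7 (0.83, adjusted p = 0.0136), CESA9 (1.02, adjusted p = 0.0225) and CESA4 (0.75, adjusted p = 0.0465) were the calls among 7 genes, with 5 higher and 1 lower adjusted over the list alone (median 0.75, adjusted p = 6.39e-04, and adjusted p = 0.6686 with an estimated correlation). OsJAZ13 (-2.44, adjusted p = 0.0493), OsJAZ3 (-2.54, adjusted p = 0.0469) and OsNAAT1 (-1.56, adjusted p = 0.0316) were lower in the null. So was OsCPS4 among the largest named changes of gs1;1, while PDX12, OsADF9, OsADF6 and BGLU12 were higher. Limma called 523 probe sets, 245 higher and 278 lower, against 20 with only the compared groups in the fit and 133 with one array set alone. Of 67 named genes followed through the alternatives 17 were called here, and each was lost in at least 1 of them. Left-out arrays decided RBCS-C (any compared array but wild type sample 629, adjusted p up to 0.1395), CESA4 (any but wild type sample 628, up to 0.1580), CESA7 (wild type sample 627, 0.0589) and CESA9 (NC2373 null samples 152 and 153, up to 0.0757). OsJAZ13 (up to 0.2466) and OsJAZ3 (up to 0.2379) were lost without null sample 152 or 153 or wild type sample 627 or 628, OsPSAG without null sample 153 or 154 or either of those wild type samples (up to 0.1607), and CAO with only the compared groups in the fit (0.1297). OsCPS4 (up to 0.1829), BGLU12 (up to 0.1843) and PDX12 (up to 0.1637) were lost without any compared array but wild type sample 629, OsADF6 without null sample 152 or wild type sample 627 (up to 0.1733), OsNAAT1 without null sample 152 or 153 or wild type sample 627 (up to 0.1610), and OsADF9 with only the compared groups in the fit (0.1619). The count was 118 without wild type sample 627, 1036 without wild type sample 629 and 148 without NC2373 null sample 152.

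Comparisons of ND8037 null with the other controls cross the array sets. The 3' minus 5' signal of actin averaged 4.86 on the ND8037 arrays and 2.85 on the others, and that of GAPDH 2.01 in ND8037 gs1;1 and 2.23 in its null, against 1.43 to 1.55 in the other groups. Genotype, normalization and RNA quality or handling cannot be told apart in any of these values. Ribosome genes were higher in NC2373 null than in ND8037 null (median 1.02, camera adjusted p = 6.95e-04), as were cell cycle genes (median 1.39, adjusted p = 0.0054). Against wild type, ND8037 null had ribosome genes lower (median -1.06, adjusted p = 0.0016), cell cycle genes lower (median -1.36, adjusted p = 0.0037) and photosynthesis genes higher (median 0.90, adjusted p = 2.42e-13). Each comparison passed 8 lists, all lost with an estimated correlation, at adjusted p from 0.2934 to 0.6250. Against wild type the chlorophyll list leaned up in camera (adjusted p = 4.91e-04) with a median of -0.46, and between the nulls the photosynthesis list leaned down (adjusted p = 6.95e-04) with a median of 0.19. Between the nulls 41833 probe sets were called, 96.1% of them higher in NC2373 null, a share of 47.4% after quantile normalization and 33.1% after centring. ND8037 null and wild type differed in 42356, of which 4.1% were higher in the null, 51.2% after quantile normalization and 67.2% after centring. The median over all probe sets was 0.52 and -0.53 in these comparisons.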

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

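The tests of explanations in this part were all chosen after the results were seen, while the tests of the differences themselves were planned. Each result here stands out because an effect differed between the insertion lines or between the mutants, by a test of that difference. The insertion lines lie in different array sets, which the test of the lines cannot separate from line.

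Between NC2373 and ND8037 the gs1;1 effect differed for 5 probe sets (102 with only the compared groups in the fit), and 5 gene lists differed by a median log2 of -0.51 for the ribosome, -0.40 for DNA replication and cell cycle, -0.49 for cell wall loosening, -0.20 for carbon skeletons and 0.24 for cytokinin, all lost at adjusted p = 0.7835 with an estimated correlation. Between gs1;1 and gs1;2 the effect differed for 5581 probe sets, and 4 lists differed by a median log2 of 1.56 for photosynthesis, 0.87 for chlorophyll synthesis, 0.50 for the ribosome and 0.47 for DNA replication and cell cycle. These were lost with an estimated correlation, at adjusted p = 0.4209 for photosynthesis and the ribosome and adjusted p = 0.3954 for the others. With 1 probe set per gene, named genes called in opposite directions with a called difference numbered 44. They were led by OsNAS1 (8.02), OsNAS2 (6.79), YSL15 (4.08), OsNAAT1 (3.39), LAC24 (-2.75) and OsSUT1 (-2.10). A probe set of RCAA1 outside this count differed by 4.78. Against NC2373 null in place of wild type, only OsNAS2 of the 4 iron genes was called lower in gs1;2. LAC24 was called higher there (1.79, adjusted p = 2.61e-04) and OsSUT1 was not (0.52, adjusted p = 0.1840). For OsNAS1, YSL15, OsNAAT1 and OsSUT1 the opposite calls, as well as the size of the difference, thus depend on the control. On the gs1;1 side OsNAS2 stood at 11.98 in NC2373 gs1;1, 9.52 in its null and 11.73 in wild type. Its rise in that line thus depends on the control too.

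For the rise of photosynthesis and chlorophyll genes in gs1;1 (medians 1.00 and 0.77), an offset common to all probe sets is argued against as the whole cause. It would move spike controls too, and these changed by -0.03 (SE 0.05, poly-A) and -0.0011 (SE 0.02, hybridization), taking them as added in equal amounts. Such an offset would also move the genes that camera compares a list with, so it could hardly give the list result. A normalization fault that varies with signal need not show in these averages and was not tested. A single array is argued against as well, since the lowest median over 11 fits that each left out 1 array was 0.87 (largest camera adjusted p = 4.64e-06), though with all arrays both lists had adjusted p = 0.55 with an estimated correlation. Shoot or leaf tissue in the gs1;1 samples cannot be told apart from plastids greening in the root, because 12 of 13 photosynthesis genes stood higher in both lines, which either could give. The null roots expressed these genes too, 12 of 13 above the median of all probe sets in each null, with RBCS-C at 10.37 and 9.52 and none of the 13 shared with another list. A greening response to lost OsGS1;1 stays a hypothesis beside it.

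The rise of ribosome and cell cycle genes in ND8037, with a ribosome median near 0 in NC2373, was weighed next. An offset common to all probe sets is argued against as the whole cause of medians of 0.53 and 0.45, since the same spike controls changed by -0.12 (SE 0.04, poly-A) and -0.04 (SE 0.01, hybridization). As above, such an offset could hardly give a camera result, and a normalization fault that varies with signal was not tested. A single array is argued against, since the lowest ribosome median in ND8037 over 6 fits that each left out 1 array was 0.46 (largest camera adjusted p = 7.44e-04), though with all arrays both lists had adjusted p = 0.7408 with an estimated correlation. Lower RNA integrity in the ND8037 null samples stays open, since the 3' minus 5' signal of actin differed by 0.03 (SD 0.12) and that of GAPDH by -0.22 (SD 0.08). A difference between the lines, which the design names, was not tested apart from these and may also account for it. Line and array set coincide here and cannot be told apart.

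Falls in gs1;2 were weighed last. Wild type samples that stood above another control are argued against as the whole cause, since each gs1;2 array in turn, held out of the choice of probe sets called lower, lay below NC2373 null over them, at medians of -0.45, -0.43 and -0.65. These medians were over 1236, 582 and 262 probe sets. The rest of the gs1;2 arrays took part in the choice. Background, growth or handling shared by the gs1;2 plants could therefore also give these values. For the 6 largest named falls other than OsGS1;2 and the iron genes they remain a candidate explanation, since 1 of the 6, OsTPP1, was called lower against NC2373 null, and OsJAZ13 and OsJAZ3 were lower in that null than in wild type. Handling or growth of the wild type samples was not tested.

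Other divisions of the samples bear on the counts. For the mean gs1;1 effect, 1 of 100 divisions, the real one, reached 7991 probe sets, a share under 0.05. The highest other gave 3109. Other divisions mix mutants with nulls, so a real effect also widens their spread and lowers their counts. Growth or handling shared by a group was not tested by these divisions. For comparisons of 3 against 3 there are 10 divisions, too few for a share under 0.05. The real one was the 1 that reached its count, with 5200 in ND8037 (highest other 2), 2310 in gs1;2 (highest other 1), 523 for NC2373 null against wild type (highest other 21), 41833 between the nulls and 42356 between ND8037 null and wild type (highest other 0 for both).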

How the results depend on the processing

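Fits of each array set alone, controls other than the planned ones within a set, and list normalizations were chosen after the data were seen, and the other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. With 2 or 3 arrays per group, a leave-one-out fit of NC2373 gs1;1 rests on 1 array, assumed to vary like the others. Array number and signal over background limit small and dim changes, and the cause of the shifts given here was not tested beyond their construction.

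A minimum of 2-fold kept 860 probe sets for the mean gs1;1 effect, 1338 for NC2373, 688 for ND8037, 570 for gs1;2, 1686 for the mutant difference, 203 for NC2373 null against wild type, 10250 between the nulls and 10349 for ND8037 null against wild type. With only the groups compared, which leaves fewer samples, counts were 2189 for NC2373, 3213 for ND8037, 102 for the line difference, 615 for gs1;2 and 20 for NC2373 null against wild type. An array set alone gave 3213 for ND8037, 1360 for gs1;2 and 133 for NC2373 null against wild type. Without dim probe sets the line difference had 2 calls, and the comparisons across array sets 22558 and 23069. Quantile normalization gave 27240 and 26748 for these. Controls that cross the sets gave 34438 for the gs1;1 groups minus wild type, 23971 for gs1;2 minus 3 controls, 35621 for gs1;1 minus gs1;2 without controls and 945 with the lines pooled, where normalization and genotype cannot be told apart. Within a set, gs1;2 gave 5849 against NC2373 null and 5577 against the mean of both controls, which ended 889 and 294 of the 2310 calls, and NC2373 gs1;1 against wild type gave 4465 and ended 1952 of 4382.

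Leaving out 1 array gave 5260 to 7600 calls for the mean gs1;1 effect, 1525 to 3754 for NC2373, 2075 to 4380 for ND8037, 1 to 22 for the line difference, 555 to 2817 for gs1;2, 3151 to 5841 for the mutant difference, 118 to 1036 for NC2373 null against wild type, 39538 to 40508 between the nulls and 40257 to 40991 for ND8037 null against wild type. The arrays that moved a count by over 1.5 times stand beside it in the report.

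Lists passing numbered 5 in gs1;1, 6 in NC2373, 5 in ND8037, 5 for the line difference, 7 in gs1;2, 4 for the mutant difference, 3 for NC2373 null against wild type and 8 in each comparison across sets. With an estimated correlation 0 passed in each. By fry these were 10 in gs1;1, 3 in NC2373, 0 for the line difference, 4 in gs1;2, 11 for the mutant difference, 0 for NC2373 null against wild type, 20 between the nulls and 19 for ND8037 null against wild type, and in the last pair its direction was opposite to that of camera for 15 of 23 lists. Quantile normalization left 2 and 4 lists across sets and centring 2 and 3, and centring gave 6 for the mutant difference.

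No named gene reversed in the alternatives counted here, 17 for gs1;1 and 12 for gs1;2, which leave out the 2-fold minimum and other controls. OsJAZ13, OsNAS1 and YSL15 lost no call in them for gs1;2. Against NC2373 null they were not called (limma adjusted p = 0.2805, 0.1204 and 0.1423). Of 52 called in gs1;1, 44 were called in every alternative, and 14 of 35 in gs1;2, 6 of 21 in NC2373, 14 of 21 in ND8037, 47 of 57 in the mutant difference, 1 of 5 in the line difference and 0 of 17 for NC2373 null against wild type. Over the fits of these 7 comparisons, leaving out arrays ended a call 286 times and added 29, fits of only the groups compared ended 44 and added 2, and quantile normalization ended 3 and added 1. Leaving the disrupted genes out of the ammonium assimilation list, chosen after the data were seen, ended its call in gs1;2 (adjusted p = 0.1727). A mean over all probe sets of a gene changed no list call in comparisons within a set.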

Other observations

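All values in this part were picked after the data were seen, and no explanation of them was tested.

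Some of the largest differences of the series lay in genes without a name. LOC4331398 stood at 11.38 ± 0.15 (n = 3) in gs1;2 and 3.03 ± 0.06 (n = 3) in wild type, a difference of 8.35 (SE 0.423, adjusted p = 4.47e-08), and its other probe set gave 8.08. It stood at 3.75 ± 1.22 (n = 3) in NC2373 null and 3.13 ± 0.10 (n = 2) in NC2373 gs1;1, and on the ND8037 arrays, which appear to have been normalized apart, at 2.53 ± 0.04 (n = 3) in the null and 3.01 ± 0.66 (n = 3) in gs1;1. In gs1;1 the largest change of any probe set was -6.45 (SE 0.373, adjusted p = 5.99e-07), in one with no gene listed here. Its level went from 10.53 ± 0.77 (n = 3) to 3.96 ± 0.16 (n = 2) in NC2373, it changed by -6.33 (SE 0.498, adjusted p = 6.38e-05) in ND8037, and it stood at 9.13 ± 0.33 (n = 3) in wild type and 8.77 ± 1.10 (n = 3) in gs1;2.

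Wild type alone stood apart in another probe set with no gene listed here. It read 5.14 ± 0.05 (n = 3) in wild type and 13.12 ± 0.05 (n = 3) in gs1;2, a difference of 7.98 that would pass for an effect of the mutation, but it also read 12.67 ± 0.11 (n = 3) in NC2373 null and 12.83 ± 0.37 (n = 2) in NC2373 gs1;1, and 12.68 ± 0.06 (n = 3) and 12.66 ± 0.06 (n = 3) on the ND8037 arrays. NC2373 null exceeded wild type there by 7.53 (SE 0.107, adjusted p = 2.26e-15). LOC4340325 divided the groups differently, at 9.60 ± 1.46 (n = 3) in gs1;2 and 4.71 ± 0.17 (n = 3) in wild type (difference 4.90, SE 0.948, adjusted p = 0.0109), at 6.28 ± 2.78 (n = 3) in NC2373 null and 4.70 ± 0.05 (n = 2) in NC2373 gs1;1, and at 9.32 ± 0.07 (n = 3) and 9.11 ± 0.16 (n = 3) in ND8037 null and gs1;1.

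OsICL, which fell by 3.78 in gs1;1, stood in gs1;2 at 9.56 ± 0.31 (n = 3) against 7.93 ± 1.00 (n = 3) in wild type, a difference that did not pass (1.62, SE 0.463, adjusted p = 0.0642), and the effects of the mutants on it differed by -5.41 (SE 0.579, adjusted p = 1.25e-04). Against NC2373 null, gs1;2 had a lower photosynthesis list (median -1.29, camera adjusted p = 1.81e-04, 7 of 13 genes lower), a lower chlorophyll list (median -0.52, adjusted p = 1.72e-04, 9 of 18 lower), a lower secondary wall list (median -0.86, adjusted p = 0.0090, 4 of 7 lower) and a lower cell wall loosening list (median -0.43, adjusted p = 0.0063, 7 of 30 lower). Each had adjusted p = 0.5106 with an estimated correlation, and none of the 4 passed against wild type. NC2373 null itself stood above wild type in the photosynthesis, chlorophyll and secondary wall lists, as given above, so these falls depend on the control.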
